A study of Mus musculus with 2 samples.

How the data were processed

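RNA of mouse spleen cells was sequenced from 1 library of mice with collagen-induced arthritis (CIA) and 1 library of healthy mice. Per the labels' protocols, total RNA was extracted with TRIzol and ribosomal RNA was depleted with Ribo-Zero. The labels do not say how many mice gave each library. The submitters' processing notes name StringTie, a transcript assembler. The aligner, the genome build, the strandedness of the libraries and the test behind the p-values are not given in the sources used here.

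The authors deposited FPKM values (fragments per kilobase of transcript and 1000000 fragments) per transcript, per the file headers, in 2 tables, with 0.0001 in place of 0. The deposited ratio (fold) equalled the CIA FPKM divided by the healthy FPKM within a relative tolerance of 0.0001 for every transcript. The log2 column deposited by the authors is the logarithm of that ratio, per the file headers. The p-value and q-value columns are the authors' own, per the file headers, and are only quoted here. In 2 damaged cells of the CIA column, the value of Gm43541 (12.3 FPKM) was missing and stood before that of AI662270 (0.257 FPKM). Each was assigned the number from the damaged cells that equalled the authors' deposited ratio multiplied by the healthy FPKM, within the same tolerance. For these 2 transcripts the check of the ratio is therefore met by construction. All 15172 annotated transcripts had the coordinates of GENCODE M21, so GRCm38 is given as the build. Columns were matched to the groups by their names, model for CIA and control for healthy.

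From these values, log2((CIA FPKM + 0.1)/(healthy FPKM + 0.1)) was computed, and transcripts with at least 0.5 FPKM in either library were kept. The pseudocount understates ratios of low transcripts. With 1 library per group no test across mice was possible, and a size rule of 2-fold was used in its place. FPKM was summed over the annotated transcripts of a gene for gene values, with the floor taken as 0. Locus sums, which add the assembled transcripts of the same locus and gene name, were added after seeing the data. The depth is unknown because FPKM keeps no counts, so no counting interval can be given. Reads of overlapping or antisense genes could not be told apart, as no strand setting is stated. The span of 35.5% of the annotated transcripts past the filter overlapped an exon of a protein-coding gene.

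A total of 15 gene lists were fixed before the data were examined, as were the filter, the size rule and the rule for named genes. In 3 lists lncRNAs were named by symbol, and 12 lists held lncRNA genes within 50 kb of listed protein-coding genes. The median of each list was placed as a percentile among 10000 random lists of the same size, matched on deciles of mean FPKM, as a description of these libraries. The named genes were the title transcript, the 10 genes of highest and the 10 of lowest ratio with at least 1 FPKM in either library and above the floor in both. They also included the 5 most abundant genes listed at the floor in the other library, each way, the 10 most abundant genes, the 5 assembled transcripts of highest and the 5 of lowest ratio, and the 2 to 4 genes per list of largest ratio in either direction, where as many had at least 1 FPKM in either library. Of the genes named by this rule, 2 are not reported here. Outside this rule, 4933439C10Rik, Gas5, Flicr, Ifngas1, Gm43921, Gm15441 and F930017D23Rik, the transcripts near Gm43541 and the hosts of intronic transcripts were chosen after their values were seen. Sequence copies were sought, for the 30 genes named by ratio or at the floor in 1 library only, with blastn 2.17.0 against the GENCODE transcripts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

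The size rule was tested on simulated data for 2765 genes, 200 of them changed, with an assumed noise SD of 0.3 on the log2 scale. It recovered 77% of genes changed 2.5-fold and 100% of genes changed 4-fold. These shares follow from the assumed noise, which 1 library per group cannot measure, and give no error rate for these libraries. The alternatives were other pseudocounts, filters, centring, a 4-fold rule, gene or transcript level and other neighbour windows. Protein-coding mRNA levels were not analysed here.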

Results

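The series compares spleen RNA from mice with collagen-induced arthritis (CIA), a model in which immunization with type II collagen provokes joint inflammation, with spleen RNA from healthy mice. There was 1 library per group, so no difference below has a replicate check, and every comparison is between 2 libraries, not between the conditions. The sample titles give day 40 for both groups, whereas the treatment label of the CIA mice gives sacrifice at day 42 after the first immunization. The measurements were FPKM values of transcripts deposited as long non-coding RNA (lncRNA), so the sequencing depth is unknown. One table held 15172 annotated transcripts of 10944 gene names, of which 4867 transcripts stood above the floor value of 0.0001 in both libraries and 8689 stood at the floor in both. GENCODE types 26 of these annotated transcripts as protein-coding, 15 as pseudogene, 2 as unprocessed and 1 as processed pseudogene, and 1 as subject to nonsense-mediated decay, and they were kept. The other held 16840 assembled transcripts that matched no annotated one, of which 12603 lay inside introns and 2733 between genes. Of these assembled transcripts, 85.6% had 1 exon and 70.4% had no strand. Coordinates are those of GRCm38.

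Among the annotated genes of the table, the highest ratio in the CIA library with the pseudocount of 0.1 FPKM belonged to Gm26825 (chromosome 5, 5781530 to 5783636), at 17.9 FPKM against 0.713 in the healthy library. Without a pseudocount, Gm11944, at 1.88 against 0.00129 FPKM, had a higher ratio. Gm26825 matched the heat shock gene Hspa8 at 99.6% identity over 1940 of its 2026 bases, so reads of Hspa8 can be counted for it. Gimap1os, antisense to an exon of Gimap1, a GTPase gene of lymphocytes, stood at 13.4 against 1.80 FPKM. Gm42763, inside an intron of the histone methyltransferase gene Setd2, stood at 2.52 against 0.242 FPKM, and Dhrs13os at 2.66 against 0.272 FPKM. At the other end, Gm37474, inside an intron of Fli1, a transcription factor gene of blood and endothelial cells, stood at 0.213 against 8.24 FPKM. C030034I22Rik stood at 0.369 against 2.04 FPKM, and Gm43413, which overlaps an exon of Rhof on the opposite strand, at 0.277 against 2.70 FPKM.

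The other genes of highest ratio were Gm11944, Gm27252, 1700018A23Rik, 9930104L06Rik, which GENCODE types as protein-coding, Gm43541 and Gm39383, with log2 ratios between 2.86 for Gm39383 and 4.29 for Gm11944. The other genes of lowest ratio were Gm34006, 1700007L15Rik, Gm39469, 2010007H06Rik, Gm26532, Gm42437 and Gm37646, with log2 ratios between -3.80 for Gm34006 and -2.04 for Gm37646. Such values near the floor depend on the pseudocount. With 0.01 and 1 FPKM, 1700007L15Rik had -5.46 and -1.35, and 1700018A23Rik had 4.32 and 1.25. Summing the annotated and the assembled transcripts of the locus took Gm11944 to 0.71, Gm27252 to 1.01 and Gm39469 to -0.05, and turned 2010007H06Rik from -2.78 to 0.52. Mir142hg, the host of the haematopoietic microRNA miR-142, was listed at the floor in the CIA library and at 14.3 FPKM in the healthy library. Gm20707, Gm11505 antisense to the myeloperoxidase gene Mpo, and Gm42470 were likewise listed at the floor in the CIA library, with 3.07, 1.62 and 1.34 FPKM in the healthy one. In the reverse direction Gm42890, Gm37468, 2610206C17Rik, Gm4285 and Gm17191 were listed at the floor in the healthy library and at 1.97, 1.78, 1.20, 1.17 and 1.15 FPKM in the CIA library. Gm37468 matched Sirpb1c at 97.0% identity over 100% of its length, so reads of the pair can be shared, and with its assembled isoform the locus stood at 4.83 against 2.75 FPKM, a log2 ratio of 0.79.

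Malat1, a nuclear lncRNA, was the most abundant gene, at 2185 FPKM in the CIA and 1798 FPKM in the healthy library. Its log2 ratio of 0.28 lay near the median of all genes and was -0.02 after centring on the median of the annotated transcripts. The snoRNA hosts Snhg3 (78.2 against 132.8 FPKM) and Snhg1 (28.2 against 47.7 FPKM) were lower in the CIA library. Of the other abundant genes, BE692007 stood at 41.3 against 29.9 FPKM and Dleu2 at 33.3 against 43.8 FPKM. Gm28967, Cct6a, AU020206, Gm20632 and Gm20628 had log2 ratios between -0.46 for Cct6a and 0.15 for Gm28967.

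Of 3068 annotated transcripts with at least 0.5 FPKM in either library, 481 were at least 2-fold higher and 188 at least 2-fold lower in the CIA library. Summed per gene, 386 of 2765 genes were higher and 116 lower. The median log2 ratio of the annotated transcripts was 0.30, a ratio of 1.23, and centring on it changed the split from 71.9% higher to 51.6% higher, with 292 transcripts higher and 274 lower. Centring on the median brings such a split near even by construction, and centring at the log2 ratio of 0.13 where the authors' deposited p-values peak left 401 higher and 220 lower. Medians were 0.29 for single-exon and 0.30 for multi-exon transcripts. By mean abundance the median was 0.41 at 0.25 to 1 FPKM, 0.26 at 1 to 2, 0.25 at 2 to 5, 0.23 at 5 to 20 and -0.02 over the 19 transcripts above 20 FPKM.

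**Figure D1:**
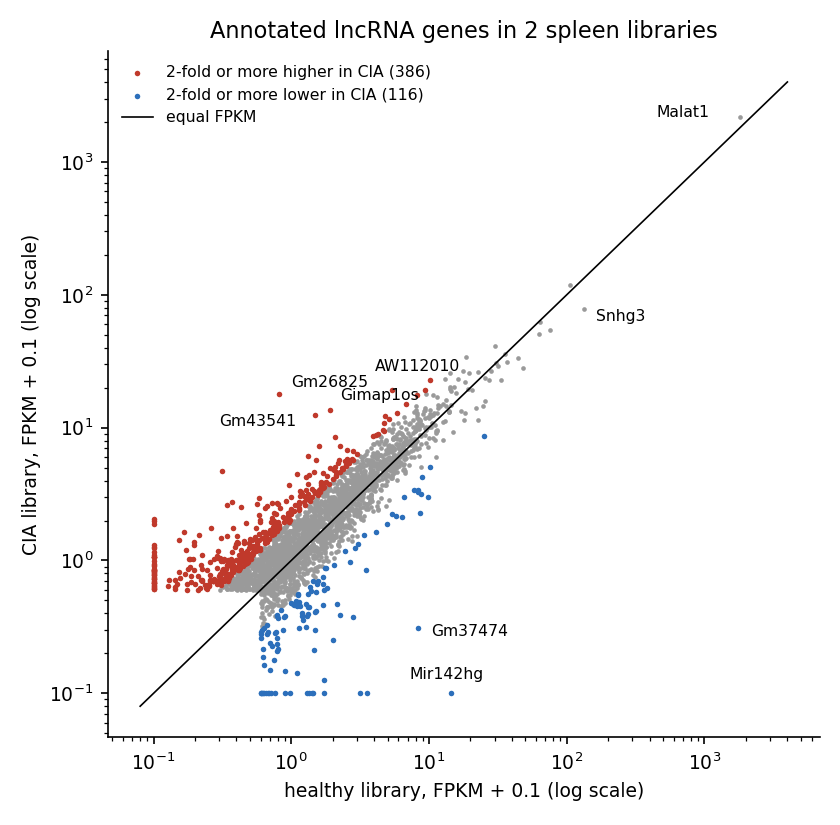
FPKM + 0.1 of each annotated gene of the lncRNA table in the healthy library (x axis, log scale) and the CIA library (y axis, log scale), 1 library per group, for 2765 genes with at least 0.5 FPKM in either library. Red points are the 386 genes at least 2-fold higher in the CIA library, blue points the 116 at least 2-fold lower, and points on the lines at 0.1 are listed at the floor in 1 library.

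The series title names the transcript ENSMUST00000197208 in connection with the balance of Th17 and regulatory T cells and the P2X7R-NLRP3 inflammasome. This transcript, of the gene Gm43541, stood at 12.3 FPKM in the CIA library and 1.39 FPKM in the healthy library, a log2 ratio of 3.06 or 8.34-fold. It has 1 exon of 581 bases at chromosome 5, 122567524 to 122568104, on the minus strand, in an intron of the ciliary transport gene Ift81 on the same strand, 174 bases from the nearest Ift81 exon. The ATP receptor genes P2rx7 and P2rx4 lie 75.8 kb and 139.4 kb away on the plus strand. By ratio it was transcript 59 of 3068, and in the authors' deposited table its p was 2.39e-05 and its q 0.00167. Its CIA value had been displaced into the cell of AI662270 and was identified from the authors' deposited ratio of 8.87. In the same region Gm43359, Gm43360 and Gm43361 near Atp2a2 had log2 ratios of -0.19, -0.26 and -0.02. The 4 assembled transcripts inside P2rx7 introns had log2 ratios of 0.13, -0.68, 1.33 and -0.33, and MSTRG.29801.1, inside a P2rx4 intron, had 0.62. Gm43301, antisense within Ift81, was listed at the floor in both libraries.

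**Figure D2:**
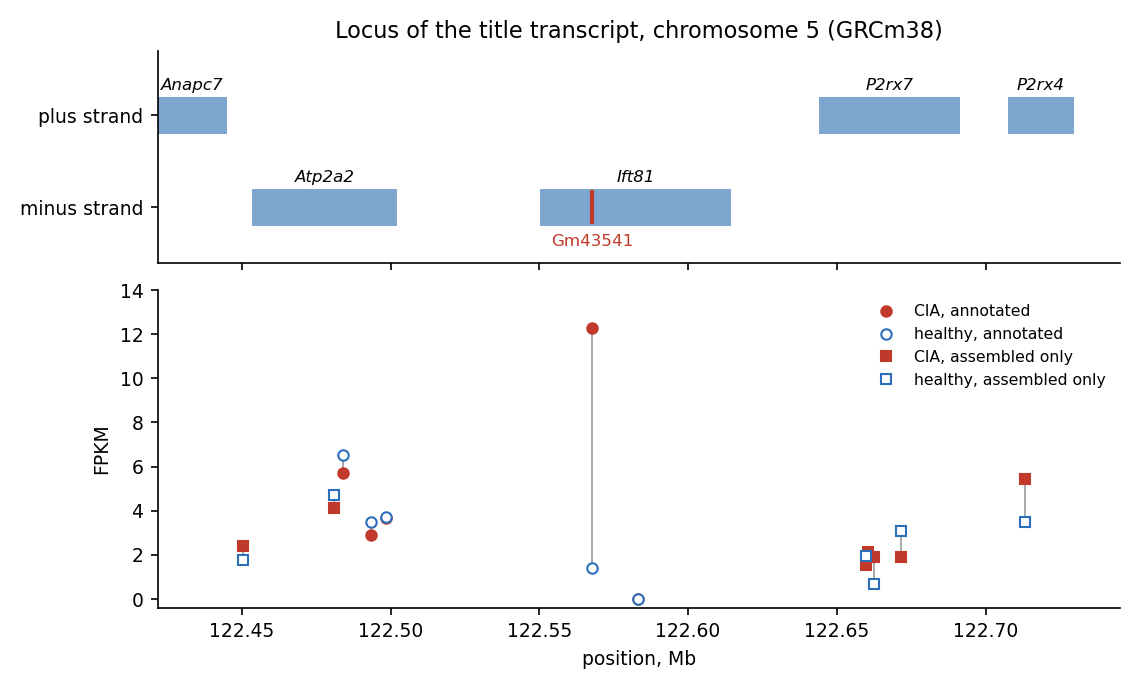
Protein-coding genes on both strands around Gm43541 (top; x axis, position on chromosome 5 in Mb, GRCm38) and the FPKM of each listed transcript (bottom; filled symbols CIA, open symbols healthy, circles annotated, squares assembled only, 1 library each). Gm43541 stands at 12.3 FPKM in the CIA library and 1.39 FPKM in the healthy library.

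Th17 cells, regulatory T cells and the inflammasome were examined through lncRNA genes lying within 50 kb of their protein-coding genes, since mRNA levels were not analysed here. The 2-fold counts of all lists were not centred. The common shift of 0.30 therefore adds to the counts of higher genes and takes from those of lower genes. Near T cell genes, the median log2 ratio was 1.03, at percentile 100 of random lists matched on abundance, and 0.73 after centring on the annotated median. Uncentred, 12 of 22 lncRNA genes were at least 2-fold higher in the CIA library and none was 2-fold lower. Examples were Gm42449 near Lef1, a transcription factor gene of naive T cells (4.38 against 0.996 FPKM), Gm44175 near Cd8a (1.80 against 0.370 FPKM) and Gm26551 near Tcf7 (4.45 against 1.59 FPKM). Of the 22, 9 lay near Satb1, a chromatin organizer of T cells, and without these the median of the other 13 was 1.24. Near B cell genes, 4 of 9 were 2-fold higher and 1 was 2-fold lower, with a median of 0.86 at percentile 99.6. Gm16553 near Fcer2a stood at 1.13 against 0.397 FPKM and 4930517J16Rik near Pax5, the B lineage factor, at 19.04 against 9.29 FPKM. With assembled transcripts of the locus added, the B cell median was 0.52, 4930597A21Rik near Ebf1 turned from 1.73 to -0.30, and 2010007H06Rik near Pou2af1, the 2-fold lower gene, turned from -2.78 to 0.52.

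Near regulatory T cell genes, 1 of 10 lncRNA genes was 2-fold higher and none lower, with a median log2 ratio of 0.63 at percentile 89.6. Bach2os stood at 2.81 against 1.19 FPKM, Bach2it1 at 6.62 against 3.42 FPKM, Gm16008 near Tnfrsf18 at 1.26 against 0.651 FPKM, and Gm36995 near Foxp3, the lineage factor of these cells, at 1.11 against 0.682 FPKM, while Flicr, also near Foxp3, stood at 0.455 against 0.536 FPKM. Near Th17 genes, none of 4 was 2-fold higher and 1 was 2-fold lower, with a median of 0.39 at percentile 51.0. 4930506C21Rik near the chemokine receptor gene Ccr6 stood at 1.36 against 1.23 FPKM. Near P2X7R-NLRP3 inflammasome genes, 3 of 7 were 2-fold higher and none lower, with a median of 0.67 at percentile 93.3. Gm28501 and Gm37080 near Nek7, whose product binds NLRP3, stood at 2.14 against 0.895 and 3.34 against 1.53 FPKM, while 4933439C10Rik near Nlrp3 stood at 2.52 against 2.44 FPKM. Gm15441 near Txnip, also 2-fold higher, stood at 0.535 FPKM in the CIA library and at the floor in the healthy library. Of the 7 genes, 3 lay near Nek7. With 1 value per coding gene the inflammasome median was 0.45, and with a 200 kb window it was 0.16, below the common shift. The medians of the regulatory T cell, Th17 and inflammasome lists lay within the central 95 percent of random lists.

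Near cell-cycle genes, none of 7 lncRNA genes was 2-fold apart in either direction before centring, yet the median log2 ratio was -0.54, at percentile 0.14. After centring on the annotated median it was -0.83. Uncentred, it was -0.27 without overlap with coding exons and turned to 0.081 with a 200 kb window. Gm45240 near the proliferation marker gene Mki67 stood at 5.89 against 11.2 FPKM and Gm44985 near Plk1 at 1.04 against 1.56 FPKM. Among 17 snoRNA host and growth-related lncRNAs, 2 were 2-fold higher and 1 lower, with a median of -0.21 at percentile 0.035. Gas5, a snoRNA host, stood at 22.8 against 33.0 FPKM and Epb41l4aos at 2.14 against 5.28 FPKM, whereas Mir17hg, the host of the miR-17 cluster, stood at 4.53 against 1.36 FPKM. As locus sums with assembled transcripts, the log2 ratio went from -1.26 to -0.63 for Epb41l4aos, the only 2-fold lower gene of this list, which brings it within 2-fold, from -0.53 to -0.27 for Gas5 and from 1.67 to 2.62 for Mir17hg. The median of the whole list went the other way, from -0.21 to -0.27. Snhg3, Snhg1 and Gas5 lie above 20 FPKM as genes, and the annotated transcripts above that level had a median of -0.02. Among 15 immune and inflammation-related lncRNAs, 4 were 2-fold higher and 3 lower, with a median of -0.20 at percentile 0.32. Ifngas1, which neighbours the interferon gamma gene, stood at 0.614 against 0.0437 FPKM, and Ttc39aos1 at 0.568 against 1.597 FPKM. AW112010, an interferon-inducible transcript, stood at 19.1 against 5.28 FPKM in its annotated form. An assembled isoform of AW112010 stood at 0.000689 against 22.2 FPKM, so the locus sum was 20.4 against 31.0 FPKM, in the opposite direction.

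The nuclear, X-linked or imprinted lncRNAs had a median log2 ratio of 0.32 over 10 genes (percentile 67.9), where Firre stood at 5.39 against 2.74 FPKM and Airn at 2.77 against 1.40 FPKM. Near myeloid genes the median was 0.29 over 9 genes (percentile 47.8), with 2 genes 2-fold lower, Mir142hg and Gm11505, both near Mpo. It was -0.38 without overlap with coding exons and -2.22 with a 10 kb window. The value of -2.22 lies midway between Gm11505, at the floor in the CIA library, and A530013C23Rik, so it rests on few genes. Near erythroid genes the median was 0.45 over 3 genes (percentile 57.6), where Bloodlinc, near Slc4a1, stood at 1.55 against 1.11 FPKM and Tnk2os, near Tfrc, at 3.68 against 2.81 FPKM. Near platelet genes it was 0.04 over 5 genes (percentile 19.6) and near interferon-response genes 0.18 over 4 genes (percentile 39.5), both below the median of all genes, 0.30, so that subtracting the shift of 0.30 alone makes them negative, at -0.26 and -0.12, and puts the myeloid median near 0. With a 10 kb window the platelet median was -0.65, which is the value of Gm43904 alone. Gm43904 near Gp9 stood at 1.94 against 3.09 FPKM and Gm12319 near Gp1ba at 2.505 against 1.698 FPKM. Gm44148 near Usp18 stood at 2.66 against 1.33 FPKM. The interferon median was 0.85 with a filter of 1 FPKM and 0.75 with a 10 kb window or without overlap with coding exons. It was 0.20 with a 200 kb window and -0.20 with no filter. Near NK and cytotoxic genes and near stromal and endothelial genes only 1 gene each passed the filter, Gm44816 at a log2 ratio of 0.72 and Gm43921 at 0.68.

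**Figure D3:**
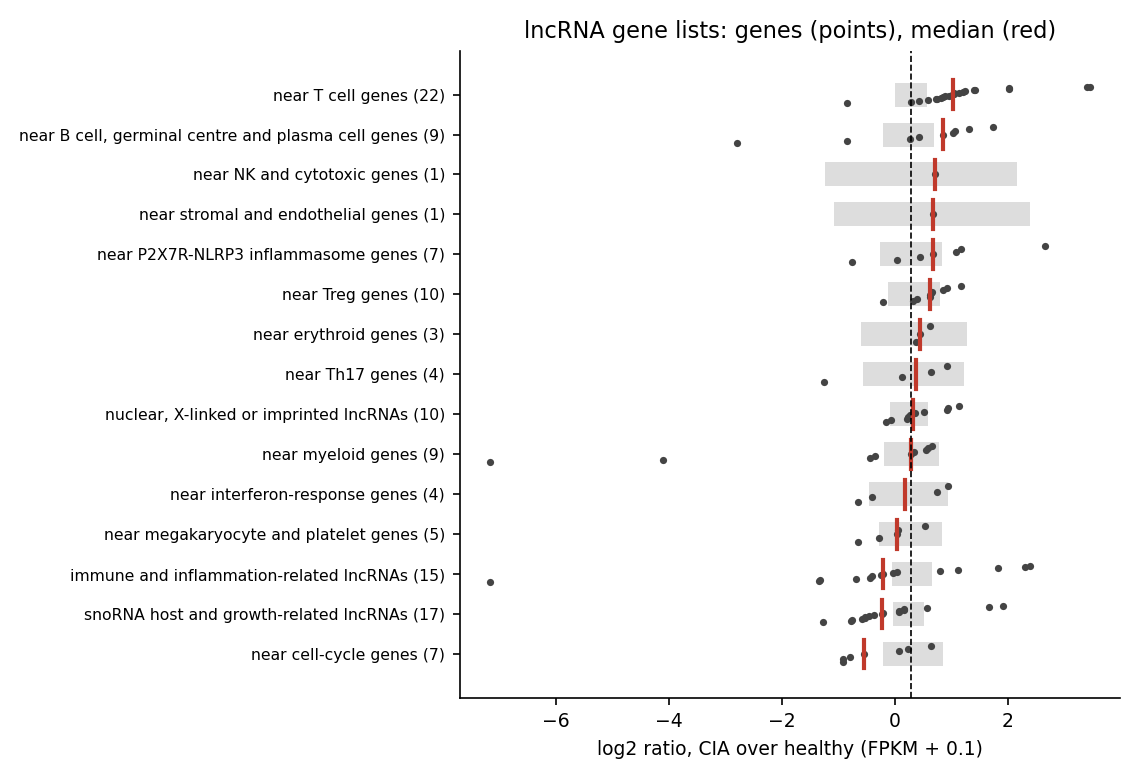
Log2 ratio (x axis; CIA over healthy library, FPKM + 0.1) of each lncRNA gene past the filter, by list, with the number of genes in brackets. Red bars are list medians, grey bars the central 95 percent of medians of 10000 random lists matched on abundance, and the dashed line the median of all genes, 0.30; the T cell median of 1.03 and the B cell median of 0.86 lie above their grey bars, the B cell median being 0.52 as locus sums, 0.60 with a 200 kb window, 0.49 with a pseudocount of 1 FPKM and 0.21 with no filter, and the cell-cycle, snoRNA host and immune medians of -0.54, -0.21 and -0.20 lie below, of which the cell-cycle median turned to 0.081 with a 200 kb window.

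Among the assembled transcripts, those of largest ratio in either direction lay mostly over genes of small structural RNAs. MSTRG.31436.2 at Rn7s6 stood at 1170 FPKM in the CIA library against 0.0429 FPKM in the healthy library, with a locus sum of 1170 against 243.8 FPKM. MSTRG.8166.2 over snRNA genes stood at 800.8 against 0.00614 FPKM, but its locus summed to 2403 against 3041 FPKM. The others were MSTRG.6995.2, MSTRG.6995.3 and MSTRG.6995.4, whose locus summed to 323.2 against 1275 FPKM. In the opposite direction MSTRG.864.5, over snRNA genes, stood at 6.16 against 9210 FPKM, with a locus sum of 4673 against 23612 FPKM. MSTRG.6453.1, spanning Snord7, stood at 2.14 against 200.1 FPKM, and MSTRG.22996.1, which shares splice sites with Slpi, a protease inhibitor gene of myeloid and epithelial cells, at 0.0935 against 16.5 FPKM. MSTRG.19220.2 is the AW112010 isoform above, and MSTRG.31401.2 stood at 0.000178 against 5.397 FPKM. Of 16773 assembled transcripts past the filter, 2887 were 2-fold higher and 1863 lower in the CIA library, with a median log2 ratio of 0.26. Centring on the annotated median changed 60.8% higher to 42.8% higher, with 1927 higher and 2576 lower, whereas centring where the authors' deposited p-values peak left 2416 higher and 2114 lower. The direction of this split thus depends on the scaling, which moves all transcripts alike.

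In the authors' deposited table of annotated transcripts, 59 had a p below 0.05, 31 higher and 28 lower in the CIA library. A q below 0.05 was given in the authors' deposited table to 12 annotated transcripts, 5 higher and 7 lower, among them Gm26825 with a p of 3.39e-09. The authors' deposited table marked 196 annotated transcripts as significant, 151 higher and 45 lower, with p-values of up to 0.211. In the authors' deposited table of assembled transcripts, 312 had a p below 0.05, 222 higher and 90 lower. Over the 11791 transcripts whose p in the authors' deposited table was not 1, the p was turned into a signed normal score. This score followed the log2 ratio with an R squared of 0.996. A 2-fold ratio went with a p in the authors' deposited table of about 0.2002 upward and 0.09997 downward. Single transcripts differed from this, as 4930517J16Rik, at a deposited log2 ratio of 1.036, had a p of 0.172 in the authors' deposited table. These p-values compare 2 libraries and hold no spread between mice.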

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

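The settings added after seeing the data were the locus sums, centring where the authors' p-values peak, transcripts whose span overlaps no coding exon, and 1 value per coding gene. No paired analysis was possible because each group had 1 library. The title transcript kept a log2 ratio above 2-fold under every setting tried, the lowest being 2.48 with a pseudocount of 1 FPKM. The medians of all annotated and all assembled transcripts moved by less than a factor of 1.5 under every setting tried, and so did the T cell list. Counts of annotated transcripts higher and lower were 86 and 56 with a pseudocount of 1 FPKM, 1023 and 508 with no filter, 251 and 111 with a filter of 1 FPKM, and 145 and 82 under the 4-fold rule. They were 313 and 111 without overlap with coding exons, a smaller set by construction. Centring on the annotated median left 292 higher, and summing per gene left 116 lower. Assembled transcripts counted 1364 higher and 923 lower with a pseudocount of 1 FPKM, and 874 and 744 under the 4-fold rule. By q below 0.05 the authors' deposited table held 12 annotated transcripts, against 59 by p. The B cell list median was 0.21 with no filter. The myeloid median was -2.22 with a 10 kb window, midway between Gm11505 and A530013C23Rik, and -0.38 without overlap with coding exons. The platelet median was -0.65 with a 10 kb window, which is the value of Gm43904 alone. The stromal median was 0 with no filter, the interferon median 0.85 with a filter of 1 FPKM, and the cell-cycle median 0.081 with a 200 kb window. Locus sums reversed 2010007H06Rik (0.52), 4930597A21Rik (-0.30) and AW112010 (-0.60). The cause was not tested where the construction does not give it. Over 152 named genes and list members, 46 moved with a pseudocount of 1 FPKM and 22 with 0.01 FPKM. Unknown depth limits every value near the floor.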

Other observations

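Assembled transcripts inside introns gave a view of the protein-coding genes that host them, a comparison chosen after the lncRNA lists had been seen. The median of lncRNA genes near T cell genes and its random lists were planned, and the test of intronic transcripts in T cell genes was set before its result was seen. The use of that planned median against a common shift, and the tests of the Satb1 locus, of the share of lymphocytes, of the title transcript, of isoforms and of near-identical genes, were chosen after the result was seen. Inside T cell genes, 31 of 38 intronic transcripts were at least 2-fold higher in the CIA library and none 2-fold lower, with a median log2 ratio of 1.39 (percentile 100 of matched random lists). The median ratios of the 5 host genes were all above the median of 0.25 over 12558 intronic transcripts past the filter: Lef1 at 1.51, Bcl11b, a T lineage factor, at 1.44, Themis, a thymocyte selection gene, at 1.43, Il7r at 0.94 and Satb1 at 0.67. Inside B cell genes the median was 0.83 over 16 transcripts (percentile 99.97), with Ebf1 at 0.91 and Pax5 at 0.83. Inside Th17 genes it was 0.71 over 42 transcripts (percentile 99.2), of which 25 lay in Rora. Inside regulatory T cell genes it was 0.50 over 35 transcripts (percentile 98.5), with Bach2 at 1.19 and Il2ra at -0.57. Inside inflammasome genes it was 0.29 over 22 transcripts (percentile 56.5), with P2rx7 at -0.10 and Tlr4 at -0.87. Transcripts of 1 gene are not independent. Counted per gene, the T cell median of 1.43 lay at percentile 99.7, among random lists of host genes not matched on abundance. On the same measure the Th17 median of 0.72 lay at 96.2, the B cell median of 0.87 over 4 genes at 96.0 and the regulatory T cell median of 0.38 at 70.8. These last 3 lay within the central 95 percent. Inside Pecam1, an endothelial and leukocyte adhesion gene and the only stromal or endothelial host, the median was 1.08 over 7 transcripts. Inside Gata1 it was -0.58 over 3 transcripts, and the 1 transcript inside Spi1 had 0.28. Inside the cell-cycle genes it was 0.27 over 2 transcripts, 1 in E2f1 and 1 in Myc.

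LncRNA genes near T cell genes stood higher in the CIA library. A shift common to all lncRNAs was excluded as the whole cause, since their median of 1.03 lay above the upper bound of 0.58 of matched random lists. The many lncRNAs of the Satb1 locus do not carry the whole pattern, since without them the median of the other 13 lncRNA genes was 1.24. With 1 value per T cell gene the median was 1.002, with 7 of 8 genes above the overall median. It lay above the bound of 0.81 for random lists of 8 genes, but these lists were not matched on abundance. That bound therefore does not allow for the higher ratios of low transcripts. More unspliced RNA of T cell genes in the CIA library is a candidate explanation, for which the intronic median of 1.39 lay above the bound of 0.49. This median cannot tell it from a larger share of lymphocytes, which could raise it as well. Lef1 and Satb1 also belong both to the intronic hosts and to the coding genes of the lncRNA list. A larger share of lymphocytes may account for the lncRNA lists near T and B cell genes alike, and it stays open. The myeloid median of 0.29 lay inside the range of random lists but depends on the setting. It was -0.38 without overlap with coding exons and -2.22 with a 10 kb window, for which no random lists were drawn. The value of -2.22 lies midway between Gm11505, at the floor in the CIA library, and A530013C23Rik, so it rests on few genes. Arthritis itself cannot be separated from the library.

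The title transcript stood 8.34-fold higher in the CIA library. A copy of most of its sequence in another annotated gene was excluded, since the best match, to 9430065F17Rik at 96.9% identity, covered 16.7% of its bases. Reads falling on that stretch stay open as a cause, since FPKM does not show where in a transcript the reads lie. Unspliced RNA of Ift81 could contribute, and it cannot be told apart because 0 assembled transcripts were listed inside Ift81. Arthritis as the cause was not tested, there being no replicate.

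Several values of the title transcript stood apart, and no explanation for them was tested. In the authors' deposited table its p was not 1 although it had 0.806 fragments per 1000000 (FPKM times length in kb) in the healthy library. The other 11790 transcripts with a p other than 1 in the authors' deposited tables all had at least 0.850 in both libraries. Between 0.8 and that value in the lower library lay 319 other transcripts. That 0 of them had a p other than 1 in the authors' deposited tables follows from how the bound was set, and adds nothing to it. Among 8354 annotated transcripts listed under a reference gene identifier and not under an assembled locus, it was the only one above 3.20 FPKM, the highest value of the others, that of 2010008C14Rik.

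Many transcripts were many-fold apart between the libraries, and arthritis as a cause was not tested. Reads moved between isoforms of 1 locus may account for part of this: in 26 of 39 annotated 2-fold genes with assembled isoforms the isoforms went the other way relative to the median shift (66.7%, exact 95% interval 49.8 to 80.9%, covering counting error only), which includes an even split and leaves this open. The shift was subtracted from the assembled sums only, and the count depends on that. Gm27252, at 3.89 annotated and 0.26 assembled, was counted as going the other way. F930017D23Rik, at -1.90 annotated and 0.027 assembled, was not. As a locus sum 33 of the 39 lay within 2-fold, which decides nothing, since the 39 were chosen for a 2-fold ratio, and Mir17hg, 2010309G21Rik, Gm30211 and Gm17494 lay further from 0 as a sum. The other 463 of the 502 2-fold genes had no such isoform, Mir142hg among them. The search for near-identical genes covered 30 genes, those named for their ratio or for standing at the floor in 1 library. Of these, 3 matched another gene over at least 50% of their length at 95% identity or more: Gm26825, Gm37468 and Gm37646. Copies of that extent were thus excluded for most of the 30, while shorter shared stretches were not. Gm39469 matched Gm32856 over 98.9% of its length at 84.6% identity. Reads of overlapping genes are not settled by this search. The spans of Gm11944, Gm42890, Gm17191 and Gm20707 overlap an exon of a protein-coding gene on the same strand. Those of 1700018A23Rik, 9930104L06Rik, Dhrs13os, Gimap1os, Gm37468, Gm43413 and Gm11505 overlap such an exon on the opposite strand. Reads of these could not be told apart either, as no strand setting is stated.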
